A study of Mus musculus with 7 samples.

How the data were processed

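Total RNA from liver was labelled with Cy3 from 0.5 microgram of RNA and hybridised to Agilent mouse arrays, 1 sample per array, per the labels' protocols. Samples were grouped by their labels into chow (n = 4) and HFD (n = 3). Each deposited scanner file gives spot intensity values: the processed signal, which is background-subtracted intensity per the file headers, the median and background signals, and flags. The headers name Feature Extraction 10.7.3.1, and the submitters' processing notes name version 9.1. The authors also deposited a table of log2 values for 1615 probes. Its normalization and its selection are not given in the sources used here. Its HFD columns were a smooth rising function of the scanner signals (Spearman's rho of at least 0.9999995 for each), so their scale is log2 and their direction that of the signal, and column medians lay between 9.55 and 9.85. The scale of the chow columns could not be set against scanner values.

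Of 39429 probes, 27234 were named through their RefSeq accession in a reference gene table of assembly GRCm38.p6, used for names only, and 12195 kept their accession. In the table, 1288 of 1615 probes were named, giving 1167 named genes. Control spots and spots with an outlier flag were left out of the scanner fit, and spots of a probe were averaged. For each gene the probe with the highest mean was used. In the table, 116 genes had over 1 probe, and probes of 1 gene had opposite signs. No spot was saturated. Between 57.0% and 66.8% of spots were well above background per array, and 75th percentiles of the processed signal ran from 758 to 2070. HFD replicate 1 had a quality measure out of range, with a mean negative control signal of 46.9 against 29.9 to 31.4 on the other arrays.

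The design written before the data were examined was a limma (3.58.1, R 4.3.3) linear model on log2 processed signals minus each array's 75th percentile, for probes well above background on at least 3 arrays. It was run as written. Because the scanner files labelled chow did not match the authors' chow columns, the diet comparison was made on the deposited log2 table, the alternative named in that design, with the same model. This choice was made after the data were examined. Genes outside the table were given a p of 1, so that Benjamini-Hochberg adjustment covered all 32451 genes on the array. Variances were moderated toward a prior (0.0353, with 2.10 degrees of freedom) taken from 19478 genes well above background on at least 2 HFD arrays. The table's own prior was set aside after a simulation of tables with 1500 changed genes, selected in the same way. False calls were 8.62% with that prior and 4.00% with the outside prior. The simulated variances were drawn from the outside prior, so the simulation favoured it in advance. These rates do not show that the outside prior suits the deposited table. In those simulated tables, with 32451 genes, the procedure called 90.4% of genes changed by 2 on the log2 scale, 69.6% of those changed by 1 and 15.1% of those changed by 0.5. With 200 changed genes it called 83.8%, 51.5% and 0% of them, and 2.15% of calls were false. With adjustment over the selected genes alone, 26.2% of calls were false with 1500 changed genes and 71.1% with 200. Adjustment over the members of 1 list was not simulated. In a simulation of the planned scanner comparison on 20899 genes, it called 88.2% of genes changed by 2, 54.5% of those changed by 1 and 0% of those changed by 0.5.

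Of 27 gene lists fixed before the data were examined, 7 had at least 5 members in the table and were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry as alternatives. In 100 simulated tables camera called the shifted list each time and called 9 of 600 unshifted lists. In those tables the genes varied independently and were not selected on the comparison. This error rate therefore does not carry over to the deposited table. Enrichment among higher and lower table genes was tested with Fisher's exact test (two-sided) against named genes well above background on at least 2 of 3 HFD arrays, with adjustment over 54 tests. That background leaves out genes expressed in chow alone. Named genes followed a rule fixed beforehand, applied to the table: the 10 higher and 10 lower genes with official symbols and the largest fold changes among those that passed, up to 4 passing members per list or else the member with the smallest p, and 18 genes named whatever their result. Of these 18, 1 is not reported here.

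A gene not well above background on any array of a group has a bound, the bright group's mean against the mean, per array, of the higher of its own value and the lowest value of probes well above background. For chow, whose flags belong to files that did not match, the highest HFD floor (4.93) stood in. It came from HFD replicate 1, the array with a quality measure out of range. The floors of HFD replicates 2 and 3 were 4.16 and 3.72. Chow values of Pnpla3, Slc22a27 and Ccr2 that are called below the floor lay above both of these. Alternatives covered background correction, scaling, filters, probe choice, variance model, array weights, slide, replicate number and leaving out each sample. Normexp used median signals, since the files give no mean signal column. A fit with scan day could not be made, because each group had a day of its own. Slide was a random block in the scanner fit alone.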

Results

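Liver RNA of male C57 mice was profiled on 1-colour Agilent arrays after 20 weeks on a high-fat diet (HFD) or on control chow, begun at 6 weeks of age. There were 7 samples, 4 from chow and 3 from HFD, with 1 array per sample. The deposited data hold a scanner file for each array, with 39429 probes, and a table of processed log2 values for 1615 of those probes. The labels give each sample as a liver of its group but do not say which animal it came from. The limma p-values therefore measure the spread between these samples. The number of arrays limits the precision of every value below.

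The scanner files and the value table did not hold the same measurements for chow. Across the 1615 probes, each HFD scanner file followed its own column of the table with a Pearson r of 0.99991 or more. The 4 scanner files labelled chow followed their own columns with r between 0.581 and 0.589, and the highest r of any of them with any of the 7 columns was 0.628. These correlations are across probes, which are not independent replicates. In the scanner files labelled chow, 11 of 20 liver genes were not well above background on any array, albumin (Alb) and apolipoprotein A-I (Apoa1) among them, while all 20 were well above background on the 3 HFD arrays. The diet comparison below therefore rests on the value table, a choice made after this mismatch was seen, and the planned comparison of the scanner files is given at the end.

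**Figure D1:**
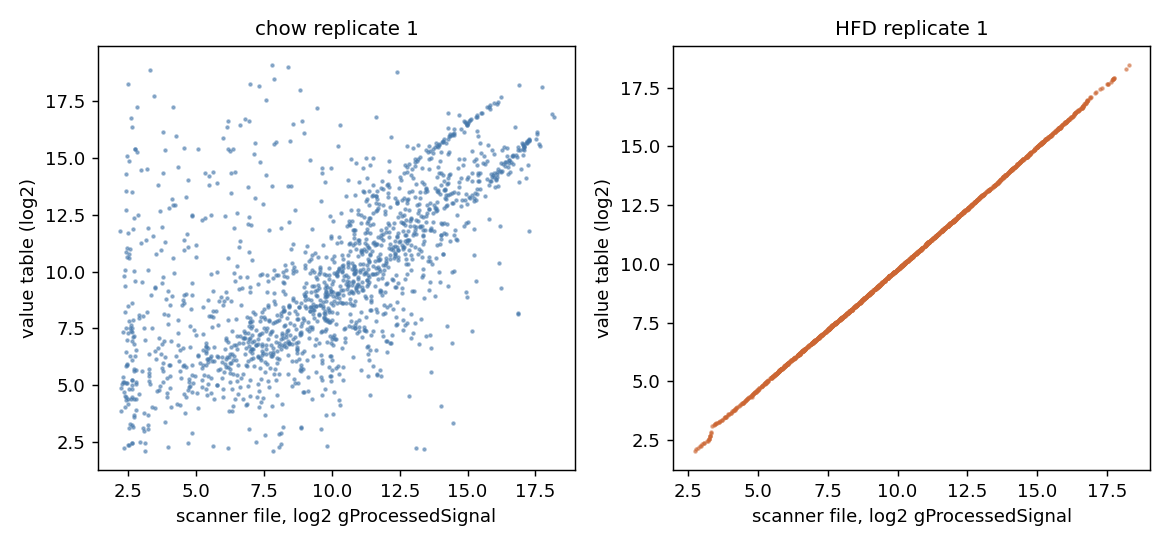
Each point is 1 of the 1615 probes of the value table, for chow replicate 1 (left) and HFD replicate 1 (right), with the log2 processed signal of the scanner file on the x axis and the log2 value of the table on the y axis. The HFD points lie on a line and the chow points scatter, with r = 0.581 for the chow array shown.

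The first question is which liver genes differed between mice fed HFD and mice fed chow. Of the measured genes, 8 of 24 of lipid droplets and fat uptake and 11 of 20 of fatty acid synthesis passed as higher in HFD, and 8 of 25 acute phase genes passed as lower. The set tests of these lists were lost with an estimated correlation (adjusted p = 0.269, 0.269 and 0.358). Cidea, a lipid droplet protein, had a log2 level of 9.29 ± 1.53 (SD, n = 4) in chow and 15.21 ± 0.23 (SD, n = 3) in HFD, a 60.7-fold difference with a log2 fold change of 5.92 and an SE of 0.77. It was 36.6-fold without chow replicate 4, whose value of 7.11 lay below the 9.37 to 10.42 of the other chow samples. Enho, which encodes the secreted peptide adropin, fell from 14.19 ± 0.39 (SD, n = 4) to 10.03 ± 0.25 (SD, n = 3), with a log2 fold change of -4.16 and an SE of 0.23. In the limma linear model, 343 genes were higher and 271 lower in HFD at an adjusted p under 0.05, with Benjamini-Hochberg adjustment over all 32451 genes on the array. Of these, 162 were higher and 152 lower by at least 2-fold. The table itself holds 801 genes that were higher and 687 that were lower. It had been selected on this comparison, since the groups did not overlap at any of its 1615 probes, where chance separates 5.71% of probes. Its p-values are therefore not independent evidence, and nothing can be said here of genes outside it. The 3 HFD arrays were scanned on 1 day, and the scan day behind the table's chow values is not known. Scan day and diet therefore cannot be told apart in this comparison. Of 63 named genes, 7 had a fold that moved over 1.5 times when 1 sample was left out. The counts of higher and lower genes fell when any 1 sample was left out, in fits with fewer samples. They were 0 and 0 without chow replicate 1, 48 and 51 without chow replicate 2, 4 and 7 without chow replicate 3, 2 and 1 without chow replicate 4, 79 and 87 without HFD replicate 1, 4 and 4 without HFD replicate 2, and 265 and 228 without HFD replicate 3.

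The 10 genes with the largest fitted increases were Cidea, Cyp2b13 and Cyp2b9, the latter a pair of cytochrome P450 genes with female-biased expression in mouse liver, Gpnmb, a glycoprotein of macrophages, and 6 others. Cyp2b9 rose by a fitted 24.4-fold, with a log2 fold change of 4.61 and an SE of 0.79, but 2 of its 4 chow values lay below the detection floor, so this fold is uncertain, and it was 46.1-fold without HFD replicate 3. Cyp2b13 was at least 13.4-fold and Gpnmb at least 5.86-fold higher in HFD, given as bounds because all 4 chow values lay below the detection floor. The bound of Cyp2b13 was 7.63-fold without HFD replicate 1 and 30.6-fold without HFD replicate 3, and that of Gpnmb was 9.94-fold without HFD replicate 3. The others were Ppp1r3g, a glycogen-targeting phosphatase subunit (log2 fold change 4.08, and 3.25 without HFD replicate 2), the transporter Slc22a27 (11.3-fold, with 2 of 4 chow values below the floor), the keratin Krt23 (log2 fold change 3.45), and, as bounds, Pnpla5 (at least 3.09-fold), the defensin Defb1 (at least 5.20-fold) and Tceal5 (at least 3.28-fold). For genes with a bound other than Cyp2b13, a place among the 10 rests on chow values below the floor. Their bounds do not set them above genes outside the 10 such as Cidec (10.9-fold). The bound of Cyp2b13 lay above that fold, but not without HFD replicate 1. Adjusted p-values of the 10 genes in limma lay between 0.0218 and 0.0471, Cidea's being 0.0257. For each of the 10, all 3 HFD samples lay above all 4 chow samples, a separation that the table's selection fixed in advance.

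The 10 genes with the largest fitted decreases were led by Enho (17.9-fold lower, adjusted p = 0.0122 in limma) and Asns, asparagine synthetase (14.8-fold lower, log2 fold change -3.88, SE 0.63). Adgrf1 (a fitted 13.3-fold) and Fam222a (a fitted 9.44-fold) were each well above background on 1 of 3 HFD arrays, and Fabp12 (6.52-fold) on 2 of 3. For Adgrf1 2 of 3 HFD values lay below the detection floor of their array, and for Fam222a 1 of 3, so their folds and places are uncertain. With these values raised to the floor the folds were 8.81 and 8.60. Adgrf1 was a fitted 8.56-fold lower without HFD replicate 1, and without HFD replicate 3 the fitted folds were 23.8 for Adgrf1 and 15.9 for Fam222a. Cadm4, a cell adhesion molecule, was 8.84-fold lower, the trefoil peptide Tff3 was 6.19-fold lower, and the remaining members were the acute phase genes Mt1, Apcs and Saa1.

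De novo lipogenesis, the making of fatty acids from acetyl-CoA, was the list with the most members in the table. Of its 20 measured genes, 15 were in the table, all higher in HFD, and 11 of them passed over all genes. When adjusted over the list alone, 15 passed. Selection of the table all but fixed such list-alone counts, here and below, since all 1488 of its genes passed adjusted over the table alone. Thrsp, a lipogenic regulator, rose 5.27-fold (log2 fold change 2.40, SE 0.27), Aacs rose 3.97-fold and the transcription factor gene Srebf1 rose 3.22-fold (adjusted p = 0.0218 in limma). Pnpla3 rose by a fitted 4.09-fold. For this gene 3 of 4 chow values lay below the floor of HFD replicate 1, but above the floors of the other HFD arrays. Fasn, fatty acid synthase, rose 2.89-fold, from 9.56 ± 0.24 (SD, n = 4) to 11.09 ± 0.29 (SD, n = 3). Scd1, stearoyl-CoA desaturase, had a log2 fold change of 1.57 with an SE of 0.33 and did not pass (adjusted p = 0.0668 in limma). The list lay higher than the other genes of the table in camera (adjusted p = 0.00196), a call that was lost at adjusted p = 0.269 with an estimated correlation. Its genes were over-represented among the higher genes of the table (Fisher's exact test, two-sided, adjusted p = 4.08e-15 over 54 tests). The background was 14046 named genes that were well above background on at least 2 of the 3 HFD arrays. Fisher's test, here and below, treats genes as independent and genes outside the table as neither higher nor lower. Its p-values therefore do not measure the spread between samples.

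Lipid droplet and fat uptake genes were also in the table on 1 side alone: 10 of 24 measured genes, all higher in HFD, of which 8 passed over all genes and 10 adjusted over the list alone. Besides Cidea, Cidec rose 10.9-fold (log2 fold change 3.45, SE 0.43), the receptor gene Vldlr 10.3-fold and the droplet coat gene Plin4 7.31-fold. Cd36, a fatty acid translocase, rose 5.60-fold, from 9.05 ± 0.61 (SD, n = 4) to 11.53 ± 0.32 (SD, n = 3). Pparg, which encodes a nuclear receptor of fat storage, rose 2.47-fold (adjusted p = 0.0180 in limma). Camera gave an adjusted p of 0.00260 for the list, and adjusted p = 0.269 with an estimated correlation. Fisher's exact test for the higher genes gave an adjusted p of 4.14e-07.

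**Figure D2:**
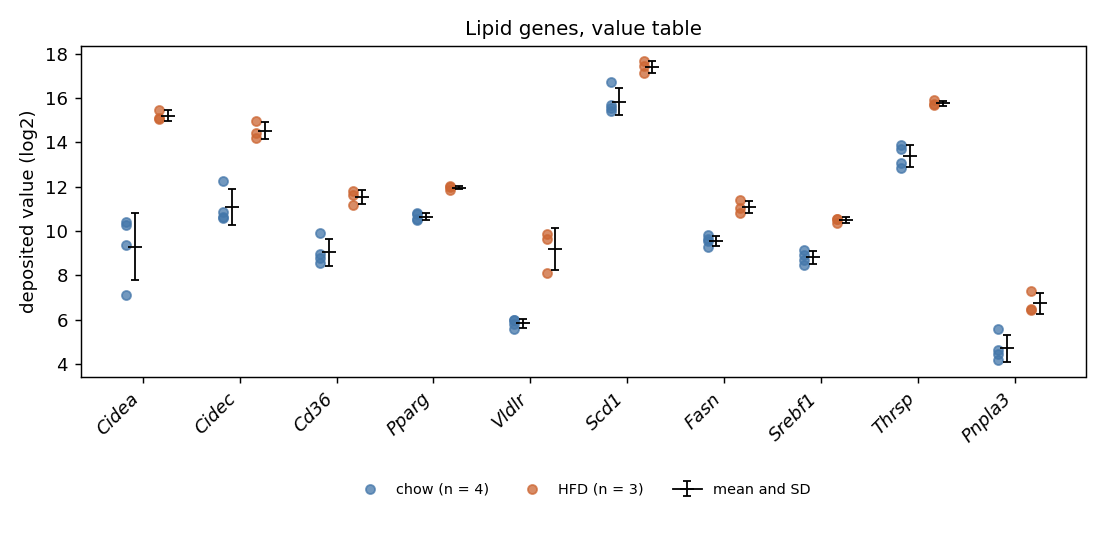
Log2 values from the deposited table for 10 lipid genes in each of the 4 chow samples (blue) and 3 HFD samples (orange), with bars for the mean and SD of each group. All 3 HFD samples lie above all 4 chow samples for every gene shown, a separation that the table's selection fixed in advance. Cidea has the widest gap, 5.92 on the log2 scale and 5.20 without chow replicate 4.

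Of 25 measured acute phase genes, many of whose products the liver secretes in inflammation, 11 were in the table. In HFD 10 of these were lower, of which 8 passed over all genes, and the remaining one, Hamp2, named after its value was seen, had a log2 fold change of 2.03 and did not pass. All 11 passed when adjusted over the list alone. Mt1, a metallothionein, fell from 18.01 ± 0.25 (SD, n = 4) to 15.10 ± 0.38 (SD, n = 3), a 7.51-fold difference (adjusted p = 0.0147 in limma). Apcs was 5.86-fold, Saa1 5.55-fold and Serpina3n 4.29-fold lower. Camera gave an adjusted p of 0.00363 for the list, and adjusted p = 0.358 with an estimated correlation, and Fisher's exact test for the lower genes gave an adjusted p of 1.66e-07.

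Stellate cell and matrix genes were in the table for 8 of 26 measured genes, all higher in HFD, with 3 passing over all genes and 8 adjusted over the list alone. Ccn2, a matrix-associated growth factor gene, rose 3.74-fold (log2 fold change 1.90, SE 0.20). Mmp2 rose from 5.89 ± 0.10 (SD, n = 4) to 6.88 ± 0.38 (SD, n = 3), and Thbs1, which encodes thrombospondin, was at least 2.91-fold higher. The list passed in camera (adjusted p = 0.0219, and 0.00647 without HFD replicate 3), with adjusted p = 0.358 with an estimated correlation, and in Fisher's exact test for the higher genes (adjusted p = 8.91e-05). Kupffer cell and macrophage markers were in the table for 4 of 22 measured genes, all higher, with 3 passing over all genes and 4 adjusted over the list alone. Besides Gpnmb, Ccr2 rose 5.09-fold, with 1 of 4 chow values below the floor, and Itgam 1.75-fold. HFD replicate 3 had the lowest HFD value of each: in HFD replicates 1, 2 and 3 the values were 8.64, 7.84 and 5.95 for Gpnmb and 12.37, 12.12 and 12.04 for Itgam, and Ccr2 had 6.63 in HFD replicate 3 and at least 7.75 in the others. The list was too short in the table for camera and did not pass Fisher's exact test (adjusted p = 0.0958). Antigen presentation genes were listed for 5 of 11, all higher, with 1 passing over all genes (H2-Eb1, 3.55-fold) and 5 adjusted over the list alone. They passed Fisher's exact test (adjusted p = 0.000750) but not camera (adjusted p = 0.0562, 0.0480 without HFD replicate 1, 0.0192 without HFD replicate 3, and adjusted p = 0.392 with an estimated correlation). Without any 1 of the remaining samples they did not pass in camera (adjusted p of 0.0546 to 0.0701). No lymphocyte, endothelial or cholangiocyte marker was in the table.

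Female-biased liver genes were listed for 5 of 21 measured genes, all higher in HFD, with 3 passing over all genes and 5 adjusted over the list alone. Besides Cyp2b9 and Cyp2b13, Abcd2 was at least 2.92-fold higher. The list passed Fisher's exact test (adjusted p = 0.00161) and not camera (adjusted p = 0.0508, and adjusted p = 0.358 with an estimated correlation). HFD replicate 3 stood apart from the other HFD samples: the values in HFD replicates 1, 2 and 3 were 10.30, 9.42 and 6.29 for Cyp2b13 and 10.12, 9.78 and 7.19 for Cyp2b9, and camera gave the list an adjusted p of 0.0114 without that sample, 0.0487 without HFD replicate 1 and 0.0308 without chow replicate 1. Without any 1 of the remaining samples the list did not pass in camera (adjusted p of 0.0511 to 0.0595). Male-biased genes were listed for 2 of 19, both lower, and Gstp1 (2.27-fold lower, adjusted p = 0.0248 in limma) passed. Xenobiotic metabolism genes were listed for 6 of 19, with 5 lower, 4 of which passed over all genes, and all 6 passed adjusted over the list alone. Cyp2c38 was 2.92-fold, Ces2a 2.46-fold and Cyp2c55 2.43-fold lower, and Cyp1a1 was at least 1.25-fold higher, being well above background on 2 of 3 HFD arrays. The list passed Fisher's exact test for the lower genes (adjusted p = 0.00335) and not camera (adjusted p = 0.0780, 0.0451 without HFD replicate 3, and adjusted p = 0.392 with an estimated correlation). Without any 1 of the remaining samples it did not pass in camera (adjusted p of 0.0647 to 0.0996). HFD replicates 1, 2 and 3 had values of 12.90, 13.22 and 13.77 for Cyp2c38 and 13.80, 14.24 and 14.67 for Ces2a.

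**Figure D3:**
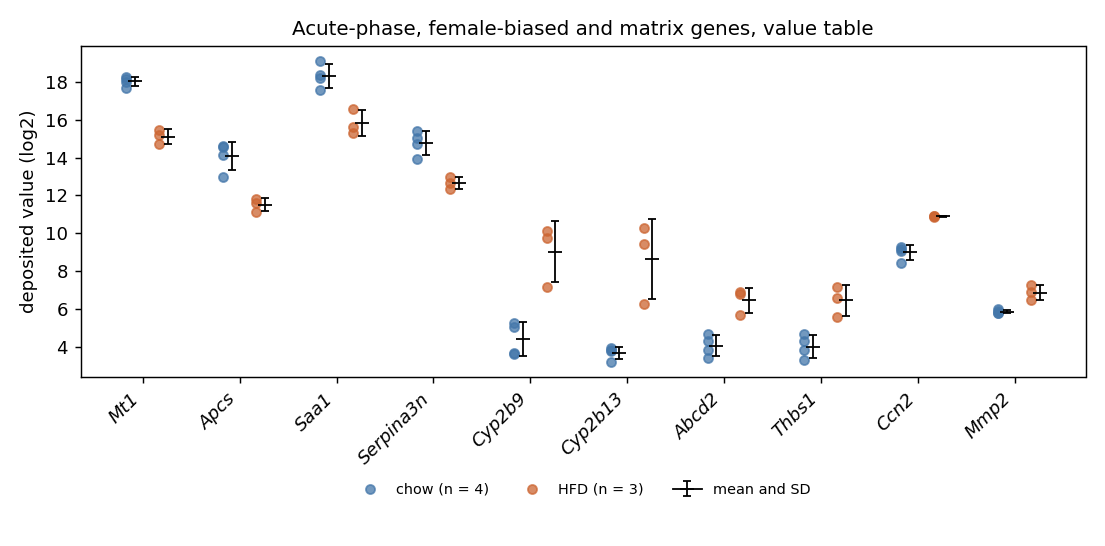
Log2 values from the deposited table for 4 acute phase genes (Mt1, Apcs, Saa1, Serpina3n), 3 female-biased genes (Cyp2b9, Cyp2b13, Abcd2) and 3 matrix genes (Thbs1, Ccn2, Mmp2), with the 4 chow samples in blue, the 3 HFD samples in orange and bars for mean and SD. The acute phase genes lie lower in HFD and the others higher.

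The remaining lists had few members in the table. Of 18 genes of the unfolded protein response, 4 were listed and passed: Asns, Derl3 (3.86-fold) and Dnajb9 (1.96-fold) were lower and Atf3 was 4.59-fold higher. Of 21 genes of glucose metabolism, 4 were listed, all higher, and Gys2 (1.87-fold), Khk (1.66-fold) and Gckr (1.43-fold) passed. Of 24 glutathione and oxidative stress genes, 4 were listed. Gstm2 rose 2.42-fold and Gstt1 1.59-fold, and Gstp1 fell. Among immediate early genes, 3 of 18 were listed, and Jun (3.27-fold) and Klf6 (2.40-fold) rose. Single members that passed were Vnn1 of fatty acid oxidation (3.64-fold higher, 4 of 32 listed), Per1 of the circadian clock (2.81-fold higher, 1 of 19), Psmb9 of the interferon response (1.89-fold higher, 1 of 23), Stard4 of cholesterol synthesis (1.60-fold lower, 2 of 24) and Serpina1a of the hepatocyte markers (1.43-fold lower, 2 of 21). Some listed genes did not pass. Ccl2, a monocyte chemokine, had a log2 fold change of 2.35 with an SE of 0.50 (adjusted p = 0.0668 in limma), and 2 of 23 inflammatory genes were listed. Abcg5 had a log2 fold change of 0.87 (adjusted p = 0.0778; 1 of 20 bile acid genes), Pf4 of 1.13 (adjusted p = 0.0760; 1 of 13 blood cell genes) and Sdhb of 0.44 (adjusted p = 0.0661; 4 of 39 oxidative phosphorylation genes). In these remaining lists every listed member passed when adjusted over the list alone, except Abcg5. No cell cycle gene and no adipose or pancreas marker was in the table. Cyp7a1, Pck1, G6pc, Fgf21, Cyp4a14, Tnf and Col1a1 had probes on the array but were not listed in the table, and Cd68 had no named probe.

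**Figure D4:**
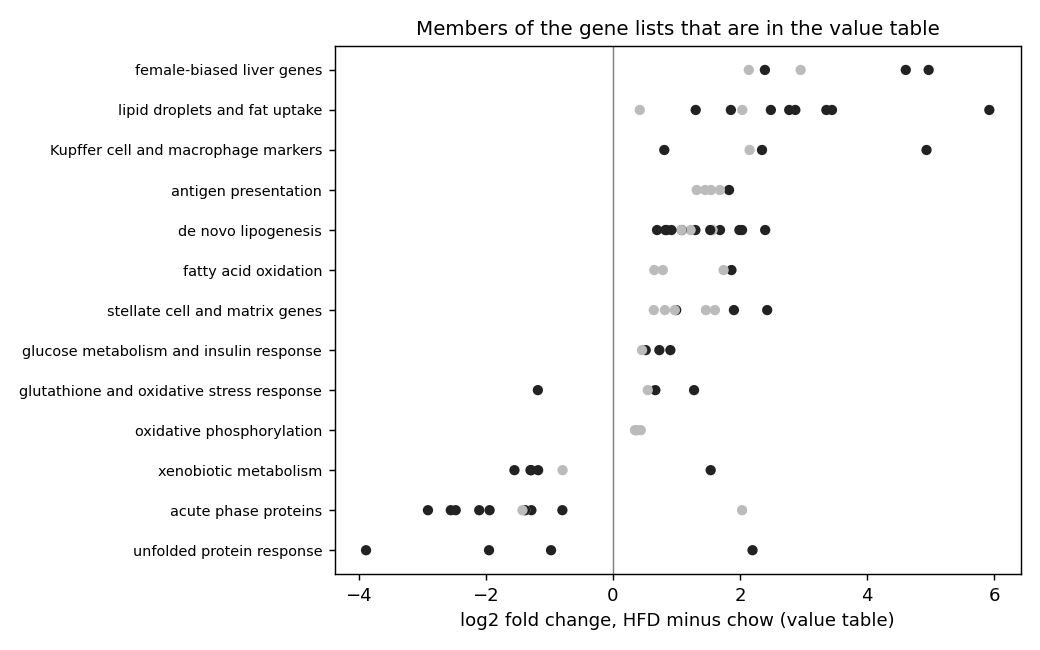
Log2 fold change, HFD minus chow, of the members in the value table for the 13 lists with at least 4 such members, ordered by their median. Each point is a gene, black where it passed at an adjusted p under 0.05 over all genes and grey where it did not. Lipogenesis and lipid droplet genes all lie above 0, and acute phase genes lie below 0 except for 1.

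The planned comparison set the scanner files labelled HFD against those labelled chow. Of 20899 genes tested in limma, 8435 were higher and 8321 lower in the files labelled HFD, 80.2% of all genes tested. The balance of higher and lower followed the scaling, with 6311 higher and 10671 lower under median scaling and 6869 and 10043 under quantile normalization. Of 27 lists, 25 passed in camera, and none of them passed with an estimated correlation, where 6 lists had an unadjusted p under 0.05. Chow and HFD scanner files correlated with r from 0.851 to 0.861 across 39429 probes, chow files with each other from 0.991 to 0.992, and HFD files with each other from 0.978 to 0.984. Genes in both comparisons had the same sign in 797 of 1441 cases (55.3%). All 4 arrays labelled chow were scanned on 1 day and all 3 HFD arrays on another, so scan day and group cannot be told apart in these files. Because the files labelled chow did not match the authors' chow values, these counts are not given as an effect of diet.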

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

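The tests of the chow scanner files were chosen after their results were seen, and those of HFD replicate 3 beforehand.

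The first pattern is the mismatch of the 4 chow scanner files with the chow columns of the value table. A swap among the 7 samples is argued against by the highest r of 0.628 with any column, and normalization by the authors by the highest Spearman's rho of 0.619 with the file's own column, where the HFD files kept their ranks. Probe names out of order are argued against by the lowest r of 0.851 with an HFD file. Signal in these files, outside the diet comparison, included 16 of 19 kidney genes well above background on all 4 files, against 5 on all 3 HFD files; Cdh16 had a level of 6.51 in the chow files and -3.62 in the HFD files relative to the 75th percentile, and Kap 5.50 and -7.05, while Alb was at -8.23 and 9.50. RNA of another tissue, with kidney as a candidate source, therefore stays open as a hypothesis; the kidney list and its test were written after kidney genes had been seen, and the groups of the design offer no biological explanation to set against it.

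On all 4 chow files, 7 of 12 brain genes, 5 of 12 skeletal muscle genes, 4 of 10 heart genes, 4 of 8 lung genes, 4 of 10 lymphoid genes, 4 of 11 small intestine genes, 3 of 10 adipose genes, 3 of 12 pancreas genes, 3 of 11 testis genes and 8 of 20 liver genes were well above background. On all 3 HFD files these counts were 7, 2, 2, 3, 8, 4, 5, 4, 2 and 20.

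The second pattern is that HFD replicate 3 lay nearer to chow than both other HFD samples at 63.7% of the table's probes. The share was 62.84% under scaling to the 75th percentile of the scanner files. For Cyp2b9 the values in HFD replicates 1, 2 and 3 were 10.12, 9.78 and 7.19 in the table. Under that scaling they were 0.41, 0.09 and -2.46, nearly the same spacing. Where the scaling nearly repeats that of the table, a similar share follows. The test therefore could not decide whether normalization by the authors caused the pattern. If chow liver RNA were mixed into the sample, higher probes would need a share of 49.6% (95% bootstrap interval 42.2 to 60.5). Lower probes would need 10.5% (4.56 to 14.5), and the intervals did not overlap. The table holds only probes whose groups do not overlap, which favours lower probes with a small share. This comparison therefore does not decide whether mixing took part. A difference between the mice or their arrays, each on a slide of its own, stays open and was not tested.

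For 4 of 63 named genes, 1 chow sample stood far from the others, by a gap over the group's range above Dixon's critical value at 95%; chance gives this for about 5% of genes. The ratio was 0.873 for Gpnmb (3.45 in chow replicate 3, the others 2.15 to 2.31), 0.875 for Gstt1 (15.53 in chow replicate 1, the others 15.81 to 15.85), 1 for Serpina1a (18.38 in chow replicate 2, the others 18.47) and 0.914 for Psmb9 (12.23 in chow replicate 2, the others 11.88 to 11.91).

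In the scanner files 1 of 35 splits of the 7 arrays, the real one, gave as many genes (16756, against 3 for the highest other). This is the smallest share that 35 splits can give, and it does not exclude chance. The real split is also the split by scan day. In the table the real split gave 614 genes and the highest other 0, also 1 of 35 splits, but the table had been selected on the real split and this comparison decides nothing.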

How the results depend on the processing

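The value table was planned as an alternative to the scanner files, and the settings tried on it were added after the data were examined; settings on the scanner files were planned, except normexp on median signals. The table's selection fixes the direction of its genes under these settings, so their signs say nothing of stability. Of 63 named genes 58 passed; 60 did with the table's own prior, 63 adjusted over the table alone, 63 with trend and robust fitting together with that prior, 60 with array weights, 57 with the mean of probes, 44 of 59 with probes well above background on all HFD arrays, 1 with no moderation and 0 with the replicate block. Without chow replicates 1, 2, 3 and 4 it was 0, 17, 3 and 3, and without HFD replicates 1, 2 and 3 it was 18, 3 and 40. Counts of higher and lower table genes were 552 and 474 with the variance prior from the table itself, 801 and 687 adjusted over the table alone, 6 and 1 with no moderation, 675 and 523 with trend and robust fitting and that prior together, and 720 and 635 with array weights. Leaving out 1 sample gave 0 to 265 higher and 0 to 228 lower, with fewer samples. The replicate block gave 0 and 0 in limma, with 801 and 687 at an unadjusted p under 0.05, which is every gene of the selected table and decides nothing. Whether the replicate numbers pair the samples is not decided by these values. Deviations of same-numbered samples correlated at -0.10, 0.14 and 0.03 in the table, and only HFD replicate 2 correlated best with its own number. No chance level was computed for these correlations.

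With an estimated correlation the adjusted p was 0.2688 for lipogenesis and lipid droplets and 0.3582 for acute phase and matrix genes. Leaving out 1 sample gave 0.000486 (without chow replicate 3) to 0.00321 for lipogenesis, 0.00168 to 0.00321 for lipid droplets, 0.00196 to 0.00505 for acute phase and 0.00647 (without HFD replicate 3) to 0.0299 for matrix genes. The table's selection fixed the direction of every member in such fits, here and for the lists below. These ranges are therefore no evidence of stability. Other lists gained the threshold under some settings: antigen presentation with array weights (0.0388), leave-one-out range 0.0192 to 0.0701; female-biased genes with array weights (0.0325) and the replicate block (0.0253), range 0.0114 to 0.0595; and xenobiotic metabolism with probes well above background on all HFD arrays (0.0143), range 0.0451 to 0.0996. In fry these lists had 0.00583, 0.00193 and 0.0121, but fry tests against no change and the selection fixed its outcome for all 7 lists. In the scanner files, normexp on median signals gave 3762 higher and 4807 lower, no filter on dim probes gave 15793 higher, the value table gave 343 and 271 with 4 lists, and an estimated correlation gave 0 lists. The cause of these changes was not tested. List tests with the slide as a block were not run. Genes dim in chow have bounds, and 33 lower probes were not well above background on any HFD array.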

Other observations

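The tests in this part were chosen after the spread of Hsd3b5 had been seen. Within the 3 HFD scanner files, which matched the authors' values, genes with sex-biased expression in liver differed between samples of the same diet. Hsd3b5, a male-biased steroid dehydrogenase gene, had levels of -3.63, -0.37 and 4.97 in HFD replicates 1, 2 and 3, relative to each array's 75th percentile on the log2 scale. Slco1a1, a male-biased transporter gene, had -1.09, 0.98 and 2.81. The female-biased Cyp2b13 had 0.60, -0.26 and -3.32, and Cyp2b9 had 0.41, 0.09 and -2.46. Of the genes well above background on at least 1 HFD array, all 18 male-biased genes were higher in HFD replicate 3 than the mean of the other two, and 13 of 14 female-biased genes were lower.

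A hypothesis is that the HFD mice differed in sex-biased liver expression. The spread alone cannot decide it: the male-biased list lay at percentile 100 of 10000 random lists matched on mean level, but 23 of 27 lists lay above the 95th percentile. Nor can the opposed shift, which was tested after the values above had been seen and rests on 1 sample. The medians of the male- and female-biased lists differed by 2.08 on the log2 scale in HFD replicate 3 against the mean of the other two, with a permutation p of 0.0001, the smallest 10000 draws can give, and the largest absolute difference of random pairs of lists was 0.58. Without Hsd3b5, Slco1a1, Cyp2b13 and Cyp2b9 the difference was 1.93 over 16 and 12 genes. Genes are not independent replicates, and 1 sample set against 2 describes these libraries; the slide of each array stays open as another candidate cause.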
